A study of Escherichia coli with 18 samples.

How the data were processed

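Total RNA was sequenced from 18 libraries: BL21(DE3), C41(DE3) and C43(DE3), hereafter BL21, C41 and C43, each with 3 replicates in each of 2 parts. In the LB part, cultures of 25 mL grew at 37 °C to an optical density of 0.4 to 0.6. In the vector part, cells carried pACYCDuet-1 and were given IPTG for 2 h. Per the labels, RNA was purified with an RNeasy kit and the LB libraries were read on an MGIseq-2000. Per the file headers, the values are counts of reads per coding sequence, made before deposit by featureCounts on the CP001509.3 annotation, strand-specific (setting 1), with a minimum mapping quality of 10. The vector table was made with version 1.6.2 and the LB table with version 1.6.4, the latter with fragments counted as pairs. The submitters' processing notes name BWA and limma; their versions were not given in the sources used here. No values other than counts were used.

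Each table held 4196 coding sequences, of which 3975 had a gene symbol and 221 a locus tag only; 5 symbols were shared by more than 1 coding sequence and these were kept apart by locus tag. No rRNA or tRNA features were in the tables. Reads outside coding sequences, unmapped or of low mapping quality stayed out of library sizes and tests. Assigned reads made up 7.47% to 13.2% of reads in BL21 with vector and IPTG, 66.7% to 72.4% in C41 and C43 with vector and IPTG, and 23.9% to 81.4% in LB. The assigned depth ran from 4.21 to 196 M (megareads) in LB and from 1.15 to 6.43 M with vector and IPTG. The common biological coefficient of variation was 0.125 in LB and 0.141 with vector and IPTG.

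Strains were compared within each part with edgeR 4.0.16 (R 4.3.3): TMM scaling, filterByExpr by group, and the quasi-likelihood F test on all 9 libraries of the part, with 6 residual degrees of freedom. P-values were adjusted by Benjamini-Hochberg, and genes with an adjusted p under 0.05 were called. The difference of a strain effect between the parts was tested as an interaction in a fit of all 18 libraries. CPM used TMM-scaled library sizes, and log2 CPM a prior count of 2. A group with 0 counts was set to a floor of 3 counts, giving fold changes as "at least"; groups with 1 to 3 counts have ratios with a 95% counting interval.

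Of 46 gene lists fixed before the data were examined, the 45 with at least 3 measured members were tested with camera from limma 3.58.1 at a preset inter-gene correlation of 0.01, which compares a list with all other genes. They were tested again with an estimated correlation, and with fry, which asks whether the genes of a list move and makes no comparison with other genes. The tests, lists, thresholds and named-gene rule were chosen before the data were examined. That rule took the 6 largest rising and 6 largest falling called genes in each comparison with BL21, and 4 and 4 in each other comparison, with separated groups, a mean CPM of at least 10 and a symbol, without the 99 transposon genes. It added up to 4 called members of each list that passed or had at least 0.5 of its members called, and a set of loci fixed in advance. Falling genes outside the runs were added by the same rule after the values were seen.

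Runs of near-absent genes were sought as at least 5 neighbouring genes with a mean BL21 count of at least 10 and at most 5% of the BL21 CPM, without transposon genes; the search and its percentages used CPM on assigned library sizes without TMM scaling. Overlap between C41 and C43 was set against 50 simulations of unchanged groups that share their controls. Labels were also exchanged between groups, in all 10 splits of 6 libraries and in 100 drawn splits for the interaction.

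Alternatives planned beforehand were other scalings (DESeq2 size factors, upper quartile), other filters, the DESeq2 1.42.0 Wald test, limma-voom, a replicate block, a fold threshold, only the 6 libraries compared, and leaving out each library. For the correlation of C41 and C43, setting each strain against a different single BL21 library was also planned. Alternatives added after the data were seen were thinning to the shallowest library and leaving out the genes of the runs. The fit was tested on simulated data with 200 changed genes. At 2-fold it recovered 88.1% in C41 against BL21 in LB and 79.1% with vector and IPTG. At 1.5-fold it recovered 73.1% and 35.8%, and there were 11 and 7 false calls in all. Only 200 genes were changed, in both directions, so these rates do not extend to the vector part, where most genes were called. Tables were prepared and figures drawn with Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. Expression levels were not compared between the parts, because plasmid, inducer, growth and run changed together.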

Results

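RNA was sequenced from 3 strains of Escherichia coli that make recombinant protein, to ask which transcriptional changes accompany C41(DE3) and C43(DE3), the hosts preferred for membrane proteins. BL21(DE3) is the parent strain; its DE3 prophage places a T7 RNA polymerase gene under a lac promoter, so that IPTG switches on genes placed behind a T7 promoter. C41(DE3) was selected from BL21(DE3), and C43(DE3) from C41(DE3), for survival during production of toxic membrane proteins. The strains are called BL21, C41 and C43 hereafter. Each strain was grown in 2 parts. In the LB part, cells without plasmid grew in rich broth at 37 °C to mid-log phase. In the vector part, cells carried pACYCDuet-1, an expression vector with T7 promoters, and received IPTG for 2 h. The 6 groups had 3 libraries each, 18 in all. Plasmid, inducer, growth and sequencing run all changed together between the parts, so only strain effects, not expression levels, were compared across them.

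Counts assigned to coding sequences in LB reached 11.4, 196 and 4.21 M (megareads) for BL21 replicates 1 to 3, 14.3, 12.8 and 11.9 M for C41, and 9.90, 12.1 and 19.0 M for C43. With vector and IPTG they reached 1.42, 1.42 and 1.15 M for BL21, 6.43, 6.36 and 5.25 M for C41, and 6.14, 5.83 and 5.84 M for C43. Unmapped reads made up 76.7% ± 4.67 (SD, n = 3) of the BL21 libraries with vector and IPTG, against 6.71% ± 0.407 for C41 and 13.5% ± 0.589 for C43. In LB the unmapped share lay between 0.0865% and 0.277%. In BL21 LB replicate 3, 68.5% of reads had low mapping quality and were not counted. Correlations of log2 counts scaled to library size (CPM) between replicates, across genes that are not independent of each other, ranged from 0.984 to 0.993 in LB and from 0.970 to 0.996 with vector and IPTG. Errors below for CPM are standard deviations over 3 libraries. For log2 fold changes they are the absolute change divided by the square root of the F statistic. Such an error is not a standard error taken from the fit, and it can be too small where a group has few counts. The p-values measure the spread between libraries labelled as replicates; intervals and floors cover counting error only. In each gene named with a value as rising or falling, all 3 libraries of one group lay above all 3 of the other, which chance gives in 10% of genes. The rule that picked the largest rising and falling genes required this separation, so for them it adds no support.

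**Figure D1:**
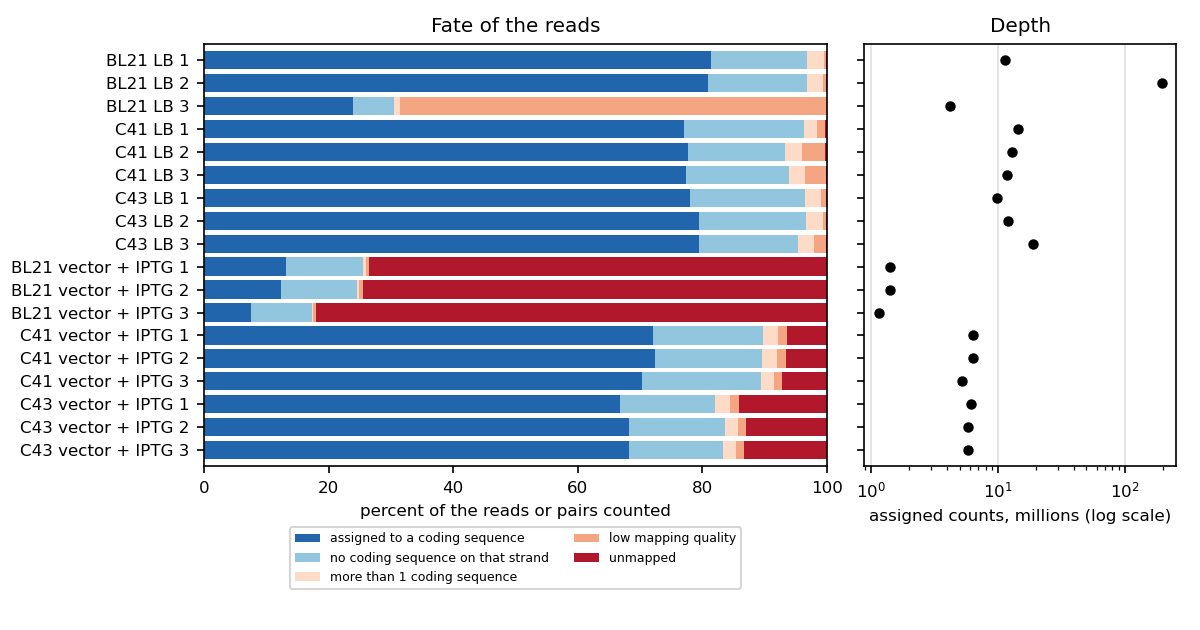
Share of reads, or of read pairs in LB, by counting outcome (percent, stacked bars) and counts assigned to coding sequences (M, log scale) in each of the 18 libraries. Unmapped reads dominate the 3 BL21 libraries with vector and IPTG, and reads of low mapping quality dominate BL21 LB replicate 3.

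C41 was compared with BL21 in LB to ask what distinguished growing C41 cells before any expression vector was present. The ribose uptake genes and 18 of 32 flagella and chemotaxis genes rose, and the T7 RNA polymerase gene fell. The ribose transporter gene rbsA (ECD_03635, CP001509.3 positions 3824025 to 3825530, plus strand) rose from 8.81 ± 3.99 to 4227 ± 326 CPM, a log2 fold change of 9.10 ± 0.25 (adjusted p = 7.12e-14). The rod gene flgB (1133588 to 1134004, plus strand) rose from 99.0 ± 20.8 to 1655 ± 161 CPM, a log2 fold change of 4.08 ± 0.17 (adjusted p = 8.2e-12). The T7 RNA polymerase gene (ECD_10004, 750421 to 753072, plus strand) fell by 4.76 ± 0.15 on the log2 scale, from 1334 ± 166 to 49.2 ± 4.98 CPM (adjusted p = 2.81e-13). Of 3808 genes tested, 737 were called, 363 higher and 374 lower in C41, and 137 of these changed at least 2-fold; without BL21 replicate 1, 488 were called. Among 45 gene lists, 13 passed the camera test, 9 towards higher and 4 towards lower expression.

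All 5 measured genes of ribose uptake and use rose in C41, also when adjusted over the list alone. The log2 fold changes were 5.02 ± 0.17 for rbsC, 4.43 ± 0.20 for rbsB, which encodes the periplasmic binding protein, and 2.81 ± 0.12 for the ribokinase gene rbsK (list adjusted p = 1.17e-12, and 0.0237 with an estimated correlation). Flagella and chemotaxis genes followed: 18 of 32 rose and 14 were not called, or 20 rose when adjusted over the list alone (list adjusted p = 1.07e-19, and 0.0237 with an estimated correlation). The list's median log2 fold change was 2.68, with 3.87 ± 0.17 for flgC, 3.73 ± 0.14 for flgA and 3.69 ± 0.14 for flgD. These were the 2 lists whose calls held with an estimated correlation between genes. The genes rbsA, rbsC, rbsB and rbsK lie next to each other on the plus strand, so their count describes the same neighbourhood. Counts of list members here and below did not take such positions into account, so they are not counts of separate events.

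Called genes of the ribosomal protein and ATP synthase lists rose by smaller amounts. Ribosomal protein genes rose in 27 of 54 cases with none lower, or 32 higher and 1 lower when adjusted over the list alone; the median log2 fold change was 0.46, with 1.21 ± 0.16 for rpmC and 0.90 ± 0.11 for rpsS (list adjusted p = 3.74e-11, and 0.116 with an estimated correlation). ATP synthase genes rose in 6 of 9 cases, with atpD at 0.67 ± 0.10 and atpH at 0.66 ± 0.10 (list adjusted p = 0.000406, and 0.265 with an estimated correlation). Of 20 cytoplasmic heat shock genes, 8 rose and 12 were not called, or 11 rose when adjusted over the list alone. Among them were the small heat shock protein gene ibpA (1.15 ± 0.14), the chaperonin genes groS (0.76 ± 0.11) and groL (0.71 ± 0.11), and htpG (0.65 ± 0.10) (list adjusted p = 7.49e-05, and 0.148 with an estimated correlation). In the list of membrane protein insertion and export, 4 of 17 genes rose, led by the export motor gene secA (0.66 ± 0.12) and secM (0.58 ± 0.11), and 1 fell (list adjusted p = 0.0123, and 0.154 with an estimated correlation).

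Called genes of the RpoS, iron uptake and methionine lists were mostly lower in C41. Genes of the RpoS general stress regulon fell in 18 of 33 cases, or 21 when adjusted over the list alone, with osmY at -1.23 ± 0.13, poxB at -1.23 ± 0.14 and ygaU at -1.04 ± 0.11 (list adjusted p = 2.41e-09, and 0.268 with an estimated correlation). Iron uptake genes of the Fur regulon fell in 17 of 37 cases and rose in 1, or 20 and 1 when adjusted over the list alone. The ferrichrome receptor gene fhuA fell by 2.11 ± 0.13, fes by 1.83 ± 0.33 and fhuF by 1.38 ± 0.20 (list adjusted p = 6.37e-08, and 0.0524 with an estimated correlation). Methionine synthesis genes fell in 5 of 13 cases, or 7 when adjusted over the list alone, with metF at -1.05 ± 0.14 and metA at -0.67 ± 0.15 (list adjusted p = 0.000452, and 0.265 with an estimated correlation). Outside these lists, the rhamnose genes rhaB (-2.28 ± 0.20) and rhaA (-1.77 ± 0.23), hyuA (-1.95 ± 0.22) and the zinc-responsive zraP (-1.85 ± 0.18) fell.

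The 4 remaining list calls in this comparison each depended on single libraries. Maltose genes (7 of 14 rose and 1 fell; list adjusted p = 0.0303) lost the call without C41 replicate 1 (0.0801). Glutamate-dependent acid resistance (3 of 13 fell, with slp at -1.52 ± 0.21 and gadE at -1.24 ± 0.23; 0.0206) lost it without C41 replicate 2 (0.0723). Branched-chain amino acid synthesis (4 of 19 rose, with ilvC at 0.78 ± 0.13; 0.0372) lost it without BL21 replicate 1 (0.0836) or 2 (0.175) and without C41 replicate 2 (0.0532) or 3 (0.105). Pyrimidine synthesis (2 of 13 rose; 0.0372) lost it without BL21 replicate 1 (0.0501) or 2 (0.152) or C41 replicate 2 (0.145). The adjusted p with an estimated correlation was 0.154 for acid resistance and 0.444 for the other lists, and the counts were the same when adjusted over the list alone.

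C43 was compared with BL21 in LB to ask the same of the strain selected in a further step. Ribose genes and 19 of 32 flagella and chemotaxis genes rose, the protease gene lon rose, and the T7 RNA polymerase gene, the lac operon and a set of neighbouring genes at 2 places in the chromosome fell. The log2 fold change was 8.91 ± 0.25 for rbsA (adjusted p = 4.33e-14) and 6.75 ± 0.21 for yhjX (ECD_03397, 3572953 to 3574161, minus strand), which encodes a transporter of a pyruvate-sensing system and rose from 6.71 ± 1.47 to 767 ± 142 CPM (adjusted p = 1.26e-13). The gene lon (ECD_00391, 427922 to 430276, plus strand) rose by 3.55 ± 0.11, from 26.5 ± 1.75 to 307 ± 5.67 CPM (adjusted p = 1.3e-13). The T7 RNA polymerase gene fell by 5.38 ± 0.15 to 32.1 ± 4.2 CPM (adjusted p = 4.33e-14). Of 3808 genes, 977 were called, 528 higher and 449 lower in C43, and 247 changed at least 2-fold. Of 45 lists 14 passed, 8 towards higher and 6 towards lower expression.

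In the lac operon, lacZ (ECD_00298, 332766 to 335840, minus strand) fell by 4.51 ± 0.19, from 165 ± 14.7 to 7.35 ± 1.74 CPM, and lacY and lacA fell by 3.83 ± 0.19 and 3.71 ± 0.18. These were 3 of 5 list members, or 4 when adjusted over the list alone (list adjusted p = 9.26e-05, and 0.048 with an estimated correlation). Both genomic copies of lacI, the repressor gene, were not called; without C41 replicate 2, which enters the shared estimate of spread, ECD_10002 was called at -1.14. Cytochrome c maturation genes fell in 7 of 7 cases, with ccmE at -5.43 ± 0.37, ccmA at -5.41 ± 0.37 and ccmC at -4.71 ± 0.37 (list adjusted p = 5.07e-09, and 0.0299 with an estimated correlation). All lie next to each other on the chromosome, so their count describes the same neighbourhood rather than separate genes. In C43, ccmE, ccmA and ccmC held 6, 9 and 8 counts over the group. Ribose genes rose in 5 of 5 cases, with rbsC at 5.20 ± 0.17 and rbsB at 4.47 ± 0.20 (list adjusted p = 6.43e-10, and 0.045 with an estimated correlation). Flagella and chemotaxis genes rose in 19 of 32 cases and fell in 1, or 19 and 2 when adjusted over the list alone (list adjusted p = 1.03e-12, and 0.048 with an estimated correlation). There flgB stood at 3.73 ± 0.17, and the serine receptor gene tsr, with 10 C43 counts over the group, at -6.97 ± 0.27. These were the 4 lists that passed with an estimated correlation.

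Called genes of several sugar, energy and translation lists mostly rose, in lists that did not pass with an estimated correlation. Maltose genes rose in 10 of 14 cases and fell in 1, with malG at 2.13 ± 0.18, the maltoporin gene lamB at 2.11 ± 0.15 and malK at 2.07 ± 0.14 (list adjusted p = 8.98e-05, and 0.247 with an estimated correlation). Ribosomal protein genes rose in 34 of 54 cases and fell in 1, or 40 and 2 when adjusted over the list alone, with a median log2 fold change of 0.51 (list adjusted p = 6.43e-10, and 0.118 with an estimated correlation). ATP synthase genes rose in 8 of 9 cases, with atpH at 0.69 ± 0.10 (list adjusted p = 0.00121, and 0.253 with an estimated correlation). Fatty acid degradation genes rose in 5 of 10 cases, or 7 with 1 lower when adjusted over the list alone, led by fadD at 1.05 ± 0.13 (list adjusted p = 0.00842, and 0.203 with an estimated correlation). Pyrimidine synthesis genes rose in 5 of 13 cases, or 7 when adjusted over the list alone, with pyrD at 1.07 ± 0.23 (list adjusted p = 0.00489, and 0.32 with an estimated correlation). Outside these lists the TCA cycle gene sucD rose by 1.02 ± 0.12.

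Called genes of the acid resistance, iron uptake and methionine lists were lower in C43. Acid resistance genes fell in 5 of 13 cases, with slp at -2.46 ± 0.22 and gadE at -1.48 ± 0.23 (list adjusted p = 0.0119, and 0.153 with an estimated correlation). Iron uptake genes fell in 9 of 37 cases, with fes at -1.39 ± 0.31 and fhuA at -1.28 ± 0.13 (list adjusted p = 0.00401, and 0.203 with an estimated correlation). Methionine genes fell in 5 of 13 cases, or 6 when adjusted over the list alone, with metE at -1.39 ± 0.11 (list adjusted p = 0.00204, and 0.3 with an estimated correlation). Heat shock genes moved both ways, 7 of 20 lower and 2 higher, or 10 and 2 when adjusted over the list alone: clpB fell by 1.09 ± 0.14 and dnaK by 0.85 ± 0.16, while lon rose. This list's adjusted p was 0.0278, and 0.32 with an estimated correlation; fry, which asks whether genes move on balance one way, gave 0.574, and the call was lost without BL21 replicate 2 (0.0554) or C43 replicate 1 (0.067). Purine synthesis genes rose in 4 of 15 cases, or 5 when adjusted over the list alone, with guaB at 0.81 ± 0.11 (list adjusted p = 0.0381, 0.44 with an estimated correlation, and 0.12 without C43 replicate 1). RpoS regulon genes, lower in C41, rose in 8 of 33 cases and fell in 1 in C43, and the list did not pass (adjusted p = 0.0599, median log2 fold change 0.18).

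**Figure D2:**
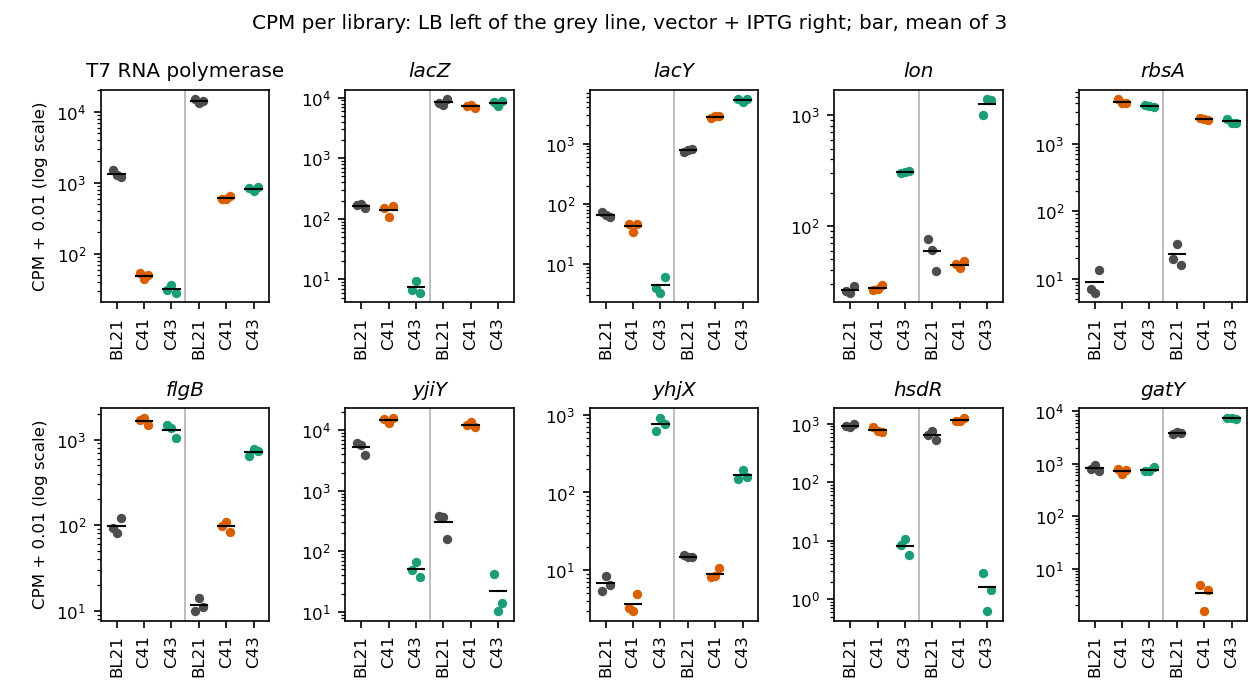
Normalised read counts (CPM) of 10 genes in every library, with LB on the left and vector and IPTG on the right; points are libraries and each bar marks the mean of 3. In LB, lon lies at 307 CPM in C43 against 26.5 in BL21, and rbsA at 4227 in C41 and 3691 in C43 against 8.81 in BL21.

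C43 was compared with C41 in LB to ask which changes separate the more derived strain. The genes yhjX, dctA, lon and narG were higher in C43, and genes of 2 neighbourhoods, around yjiY and from yojO to apbE, were near absent there. The log2 fold change was 7.73 ± 0.22 for yhjX (adjusted p = 8.7e-14), 3.57 ± 0.12 for the C4-dicarboxylate transporter gene dctA, which rose from 326 ± 11.2 to 3878 ± 202 CPM (adjusted p = 1.54e-13), 3.47 ± 0.11 for lon and 2.40 ± 0.15 for narG. The pyruvate transporter gene yjiY (ECD_04220, 4496245 to 4498395, minus strand) fell by 8.19 ± 0.26, from 14747 ± 1447 to 50.6 ± 14.4 CPM (adjusted p = 1.45e-13). Its neighbours yjiX and yjiA fell by 7.88 ± 0.29 and 7.71 ± 0.23, and the restriction gene mcrB by 7.03 ± 0.26. Of 3808 genes 600 were called, 333 higher and 267 lower in C43, and 170 changed at least 2-fold. The balance turned without C41 replicate 2, with 285 higher and 318 lower.

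Runs of adjacent genes with almost no reads accounted for the largest falls in C43 and, with vector and IPTG, in C41. A run was called where at least 5 neighbouring genes with a mean BL21 count of 10 or more each held at most 5% of the BL21 CPM. In C43, both parts showed a run from mcrC to lgoT (CP001509.3 positions 4483222 to 4513098, 29.88 kb, 24 annotated genes). It covers the hsdR-mcrB restriction genes, the yjiA to yjiY genes, hydroxyphenylacetate genes and tsr. The 22 of these used in the search, which left out transposon genes, held 3157 C43 counts in LB, 0.863% of the BL21 CPM. With vector and IPTG the run was split at yjiY into mcrC to yjiX (0.237% of the BL21 CPM) and hpaC to lgoT (0.219%); yjiY itself kept 5.37%. A further C43 region with vector and IPTG ran from ccmF to apbE (2186611 to 2205299, 18.69 kb), with the cytochrome c maturation and periplasmic nitrate reductase genes, mqo, eco and ada. Of its 20 annotated genes, the 17 with a mean BL21 count of 10 or more held 28 C43 counts against 4247 in BL21. In LB the same rule reached only the part from yojO to apbE (2197256 to 2205299, 8.044 kb, 1.03% of the BL21 CPM). Counts of about 1% of BL21 in C43 bound the fold changes measurable in the genes of the LB runs.

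C41 had a run only with vector and IPTG, from wcaN to ECD_02037 (2012466 to 2085714, 73.25 kb, 63 annotated genes), covering colanic acid, multidrug efflux and galactitol genes. Of 44 run genes with a mean BL21 count of 10 or more, 21 had 0 counts in all 3 C41 libraries, and the 44 together held 663 C41 counts against 68876 in BL21, 0.208% of the BL21 CPM. In LB the same genes, pooled, stood at 107.6% of the BL21 CPM in C41 and 140.0% in C43. Under vector and IPTG the pooled value in C43 was 332%, with the galactitol genes gatD and gatC at 4237% and 4035% but mdtA at 30.3% and yegQ at 29.5%.

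**Figure D3:**
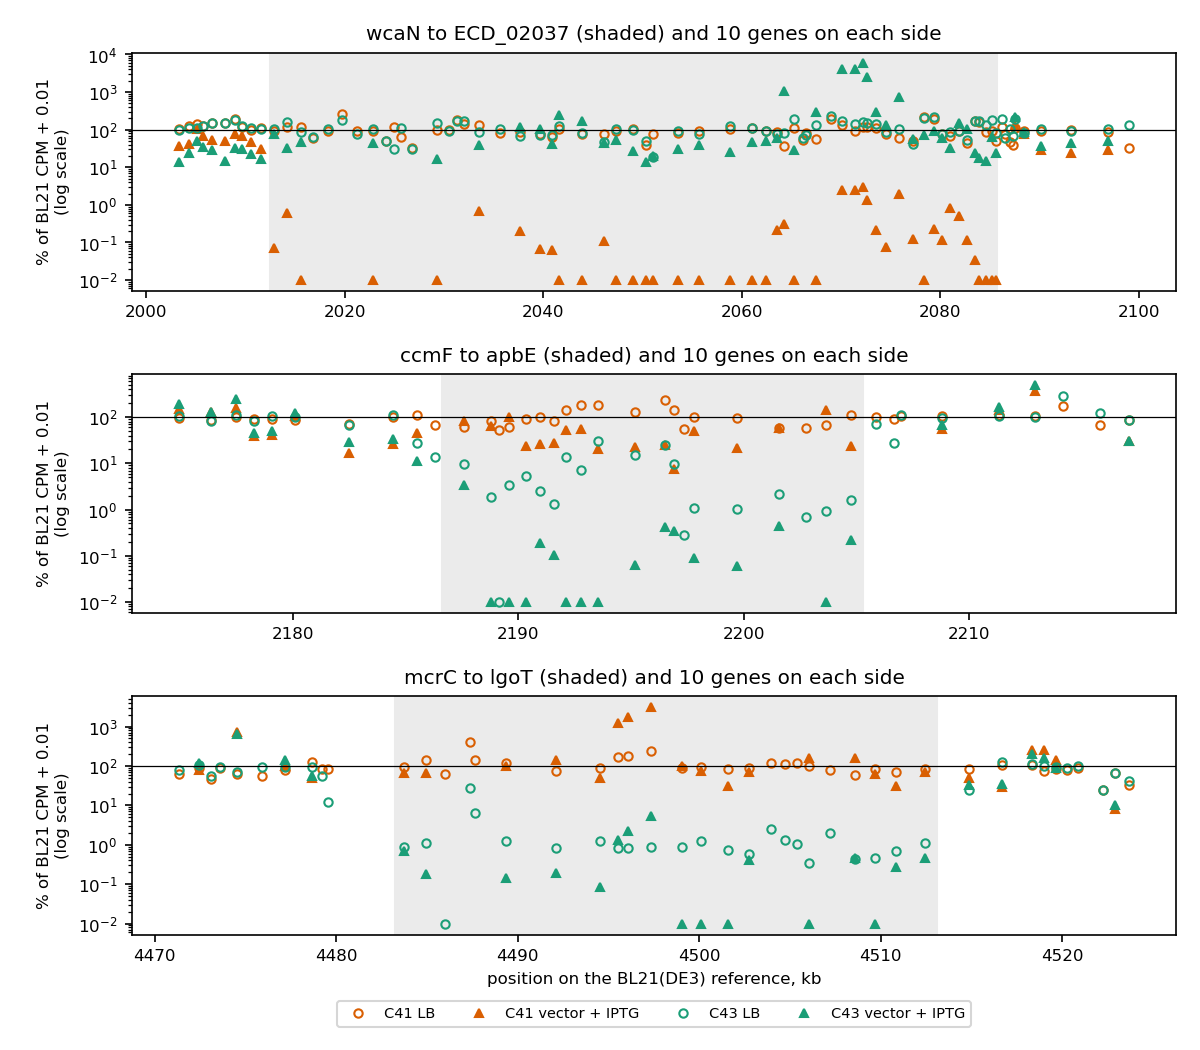
CPM of each gene as a percentage of BL21 (log scale, 0.01 added) along 3 chromosome regions of CP001509.3, for C41 and C43 in each part, with the run shaded and 10 genes drawn on each side. The mcrC to lgoT region is near absent in C43 in both parts, and the wcaN to ECD_02037 region in C41 with vector and IPTG alone.

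The changes of C41 and C43 against BL21 in LB overlapped. Both strains had 238 genes higher and 156 lower, where 50.3 and 44.1 would be shared if calls were independent, and 36 genes moved in opposite directions. The shared BL21 libraries can raise this overlap. Simulations of unchanged groups do not measure by how much, because they held no changed genes. The correlation of log2 fold changes across 3808 genes was 0.472, and 0.694 without the genes of the runs; genes are not independent replicates. Because both strains share the BL21 libraries, groups simulated without any change gave a correlation of 0.483 ± 0.0204 (SD, 50 simulations) but a covariance of 0.0213 against the observed 0.221. With each strain set against a different single BL21 library, the correlation was 0.366 (mean of 6 choices). This value used differences of log2 CPM rather than fitted fold changes, so the measure changed as well as the controls.

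With vector and IPTG, C41 was compared with BL21 to ask how the strains differed once the expression machinery was induced. Ribose, central metabolism, respiration, RpoS and heat shock genes mostly rose in C41, histidine synthesis genes and the T7 RNA polymerase gene fell, and the genes of the 73.25 kb run were near absent. The T7 RNA polymerase gene stood at 14183 ± 759 CPM in BL21 and 606 ± 37.9 in C41, a fall by 4.55 ± 0.12 on the log2 scale (adjusted p = 2.07e-11). The ribose permease gene rbsC rose by 7.17 ± 0.27 (adjusted p = 1.7e-10), from 65.9 ± 27.8 to 9551 ± 476 CPM. The acid resistance regulator gene gadE rose by 7.09 ± 0.30 (adjusted p = 5.49e-10), from 2.26 ± 1.17 to 311 ± 77.3 CPM. Further large rises were those of rbsA (6.67 ± 0.22), yjdN (6.49 ± 0.33) and the threonine dehydratase gene tdcB (6.03 ± 0.26). Of 3909 genes, 3022 were called, 1519 higher and 1503 lower, and 2079 changed at least 2-fold; upper-quartile scaling gave 1249 higher and 1819 lower.

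Beside all of these BL21 values stand shallow libraries, in which 76.7% of reads were unmapped and the assigned counts were 1.15 to 1.42 M. Upper-quartile scaling moved the median log2 fold change of all genes in C41 against BL21 from -0.04 to -0.35, and in C43 against BL21 from -0.07 to -0.19. Of 45 lists, 17 passed in C41, 11 towards higher and 6 towards lower expression. With an estimated correlation 0 lists passed camera in either strain, 8 in C41 and 7 in C43 having an unadjusted p under 0.05, while fry called 42 lists in C41 and 35 in C43. For the lists that passed, counts adjusted over the list alone were the same as over all genes, except where stated.

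Most genes of the respiratory chain, ATP synthase, glycolysis and TCA cycle lists were higher in C41. Respiratory chain genes rose in 22 of 25 cases and fell in 3, with a median log2 fold change of 2.18 (list adjusted p = 0.000129, and 0.219 with an estimated correlation). The complex I genes nuoK, nuoF and nuoL stood at 5.02 ± 0.36, 4.92 ± 0.17 and 4.80 ± 0.15. ATP synthase genes rose in 8 of 9 cases and fell in 1, with atpG at 4.21 ± 0.19 and atpH at 3.66 ± 0.12 (list adjusted p = 0.00255, and 0.219 with an estimated correlation). Glycolysis genes rose in 15 of 16 cases, with eno at 4.17 ± 0.14, fbaA at 4.08 ± 0.12 and tpiA at 4.08 ± 0.13; the exception, fbaB (-5.26 ± 0.34), lies in the run (list adjusted p = 0.000259, and 0.219 with an estimated correlation). TCA cycle genes rose in 14 of 18 cases and fell in 2, with sucC at 3.54 ± 0.19 and sucD at 3.53 ± 0.19 (list adjusted p = 0.00699, and 0.414 with an estimated correlation). Ribose genes rose in 5 of 5 cases (list adjusted p = 0.00358, and 0.347 with an estimated correlation).

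Most genes of the RpoS, heat shock and phosphate starvation lists were also higher in C41. RpoS regulon genes rose in 28 of 33 cases and fell in 2, with yjbJ at 5.30 ± 0.27, psiF at 4.36 ± 0.22 and the catalase gene katE at 3.81 ± 0.15 (list adjusted p = 1.42e-06, and 0.219 with an estimated correlation). Heat shock genes rose in 14 of 20 cases and fell in 1, with hslV at 4.49 ± 0.29, ibpA at 4.21 ± 0.33 and groS at 3.99 ± 0.24 (list adjusted p = 0.00723, and 0.5 with an estimated correlation). Phosphate starvation genes rose in 11 of 16 cases and fell in 3, with ugpE at 3.54 ± 0.30 and ugpB at 3.25 ± 0.18 (list adjusted p = 0.0269, and 0.219 with an estimated correlation). Pyrimidine synthesis genes rose in 11 of 13 cases and fell in 1, with pyrB at 4.43 ± 0.16 (list adjusted p = 0.0178, and 0.219 with an estimated correlation). Genes of lists that did not pass also rose, among them the Cpx envelope stress gene cpxP (5.28 ± 0.21), the bacterioferritin gene bfr (4.95 ± 0.15), the sulfate assimilation genes cysH (4.28 ± 0.23) and cysI (3.81 ± 0.19), rho (3.67 ± 0.13) and secA (2.83 ± 0.12).

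Histidine synthesis genes fell in 8 of 8 cases, with hisG at -5.04 ± 0.26, hisC at -4.81 ± 0.22 and hisD at -4.79 ± 0.17 (list adjusted p = 0.000479, and 0.406 with an estimated correlation). Within the run, yegQ was at least 956.5-fold lower, yegI at least 267-fold and yegE at least 177-fold, each with 0 counts in C41 against a floor of 3 counts over the group. The galactitol gene gatY, at 3892 ± 116 CPM in BL21, changed by -10.15 ± 0.29 and dcd by -10.42 ± 0.22. In C41, gatY held 57 counts over the group and dcd 6. The gene asmA, with 1 to 3 C41 counts, was lower by a ratio of 1253 (95% counting interval 427.8 to 6088). Colanic acid genes fell in 17 of 18 cases (list adjusted p = 0.00014, and 0.219 with an estimated correlation). The median was -6.60 as fitted and -4.41 with the 11 genes at 0 set to their bounds. This list held wzx (ECD_01943), which lies outside the run between vioA and rmlC, in place of wzxC (ECD_01952). Multidrug efflux genes fell in 13 of 21 cases and rose in 3 (0.0314, and 0.219 with an estimated correlation), and galactose and mannose-type transport genes fell in 9 of 14 and rose in 2 (0.0314, and 0.406 with an estimated correlation). Without the genes of the runs these 3 lists gave 0.56, 0.387 and 0.56, and galactose transport also lost its call without BL21 replicate 2 (0.0551). Outside the run, chosen after the values were seen, yneM (-5.74 ± 0.55), dgcZ (-5.74 ± 0.19), yqjI (-5.65 ± 0.24), hokD (-5.42 ± 0.16) and mokB (-4.97 ± 0.19) were, with hisG, among the genes that fell furthest.

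The other 4 list calls in C41 with vector and IPTG were near the threshold. Ribosomal protein genes fell in 29 of 54 cases and rose in 9, with rpsP at -2.06 ± 0.13 and rpsA at -1.79 ± 0.13; the adjusted p was 0.0314, 0.636 with an estimated correlation, and 0.0963, 0.0575 and 0.0661 without BL21 replicate 3, C41 replicate 1 and C41 replicate 2. Phage shock genes fell in 6 of 7 cases and rose in 1, with pspD at -3.30 ± 0.20 and pspC at -3.29 ± 0.22. Their adjusted p was 0.0408, 0.347 with an estimated correlation, 0.078 under upper-quartile scaling, and 0.052 and 0.0544 without BL21 replicates 1 and 2. Iron-sulfur cluster genes rose in 10 of 11 cases, with fdx at 2.30 ± 0.12; the adjusted p was 0.0408, 0.329 with an estimated correlation, 0.0676 under upper-quartile scaling, and 0.0548 and 0.0524 without BL21 replicates 1 and 2. Acid resistance genes rose in 7 of 14 cases, with mdtE at 4.74 ± 0.23. Their adjusted p was 0.0426, 0.627 with an estimated correlation, and between 0.0524 and 0.164 without any single library except BL21 replicate 1. For several lists that did not pass the summaries differed in sign: maltose genes had a median of 0.24, a mean of -0.08 and a fall by fry, pyruvate-sensing genes a median of -0.42 and a mean of 0.35, and glycerol genes a median of 0.03 and a mean of -0.24.

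C43 was compared with BL21 in the same way with vector and IPTG. Respiration, TCA cycle, RpoS and flagellar genes mostly rose in C43, and histidine synthesis, SOS and ribosomal protein genes mostly fell, beside the near absence of the genes of its runs. The T7 RNA polymerase gene stood at 828 ± 54 CPM in C43, a log2 fold change against BL21 of -4.10 ± 0.12 (adjusted p = 4.17e-11). The ribose genes rbsC and rbsA rose by 6.62 ± 0.26 (adjusted p = 3.84e-10) and 6.55 ± 0.22 (adjusted p = 1.28e-10), and the hook gene flgD by 6.38 ± 0.30 (adjusted p = 1.62e-09), from 20.9 ± 11.3 to 1787 ± 177 CPM. The galactarate genes garL (7.24 ± 1.25) and garR (6.36 ± 1.08) and the tryptophanase leader tnaC (6.85 ± 0.87) rose with a wide spread, garL at 5937 ± 6657 CPM in C43. Of 3909 genes, 2846 were called, 1386 higher and 1460 lower, and 1759 changed at least 2-fold; upper-quartile scaling gave 1278 higher and 1589 lower. Of 45 lists 14 passed, 9 towards higher and 5 towards lower expression.

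Respiratory chain genes rose in 22 of 25 cases and fell in 1, or 23 and 1 when adjusted over the list alone, with nuoE at 5.18 ± 0.25, nuoL at 5.18 ± 0.15 and nuoF at 5.08 ± 0.17 (list adjusted p = 1.68e-07, and 0.194 with an estimated correlation). TCA cycle genes rose in 16 of 18 cases, with sucC at 3.83 ± 0.19 and fumC at 3.59 ± 0.18 (list adjusted p = 8.64e-05, and 0.374 with an estimated correlation). Glycolysis genes rose in 13 of 16 cases, with pykF at 3.58 ± 0.17 and eno at 3.44 ± 0.13 (list adjusted p = 8.64e-05, and 0.2 with an estimated correlation). ATP synthase genes rose in 8 of 9 cases and fell in 1, with atpG at 2.97 ± 0.18 (list adjusted p = 0.0039, and 0.194 with an estimated correlation). RpoS genes rose in 27 of 33 cases, with psiF at 3.92 ± 0.22 (list adjusted p = 1.68e-07, and 0.214 with an estimated correlation). Flagella and chemotaxis genes rose in 19 of 32 cases and fell in 7, with flgE at 6.11 ± 0.31 and flgG at 6.02 ± 0.21 (list adjusted p = 0.0039, and 0.47 with an estimated correlation). Heat shock genes rose in 16 of 20 cases and fell in 1, with lon at 4.40 ± 0.22, hslV at 3.66 ± 0.29 and groS at 3.62 ± 0.24 (list adjusted p = 0.000323, and 0.47 with an estimated correlation). Phosphate starvation genes rose in 11 of 16 cases and fell in 2, with phoH at 3.83 ± 0.19 (list adjusted p = 0.0226, and 0.2 with an estimated correlation). Ribose genes rose in 5 of 5 cases (list adjusted p = 0.00115, and 0.367 with an estimated correlation). The galactitol genes gatB (6.33 ± 0.43), gatD (5.88 ± 0.37) and gatC (5.81 ± 0.34) also rose, as did tnaA (6.14 ± 0.72), secA (3.49 ± 0.13), yhjX (3.48 ± 0.16) and dctA (2.64 ± 0.13).

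Histidine synthesis genes fell in 8 of 8 cases, with hisG at -4.74 ± 0.26 and hisC at -4.61 ± 0.22 (list adjusted p = 0.000193, and 0.415 with an estimated correlation). SOS DNA damage genes fell in 16 of 21 cases and rose in 3, with lexA at -1.99 ± 0.15 and dinG at -1.47 ± 0.11 (list adjusted p = 0.012, and 0.194 with an estimated correlation). Ribosomal protein genes fell in 34 of 54 cases and rose in 7, with rplC at -2.46 ± 0.26 and rpsP at -2.13 ± 0.14 (list adjusted p = 0.0143, and 0.673 with an estimated correlation). Cytochrome c maturation genes fell in 8 of 8 cases, with a median of -6.31 as fitted and -5.24 with 3 genes at 0 set to their bounds (list adjusted p = 9.12e-05, and 0.171 with an estimated correlation). These neighbouring genes lie in or next to the ccmF to apbE region. In the runs, napH was at least 168.6-fold lower, hpaA at least 118-fold and ccmB at least 82.1-fold; napA, with 1 to 3 C43 counts, was lower by a ratio of 1379 (95% counting interval 380.7 to 11410.0). The gene eco, with 5 C43 counts over the group, fell by 9.69 ± 0.26. The colanic acid list held wzx (ECD_01943, between vioA and rmlC), at -2.28 ± 0.16, in place of wzxC (ECD_01952). Genes of this list fell in 10 of 18 cases and rose in 1, or 9 and 1 when adjusted over the list alone. Their adjusted p was 0.0277, 0.45 with an estimated correlation, 0.596 without the genes of the runs, and 0.0502 and 0.058 without BL21 replicates 1 and 2. Outside the runs, chosen after the values were seen, yneM (-5.33 ± 0.53), mgtL (-4.77 ± 0.53), hisD (-4.58 ± 0.17) and the prophage gene gam (-4.45 ± 0.21) fell among the furthest. Anaerobic respiration genes, a list that did not pass, had a median of 0.12, a mean of -0.94 and a fall by fry.

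**Figure D4:**
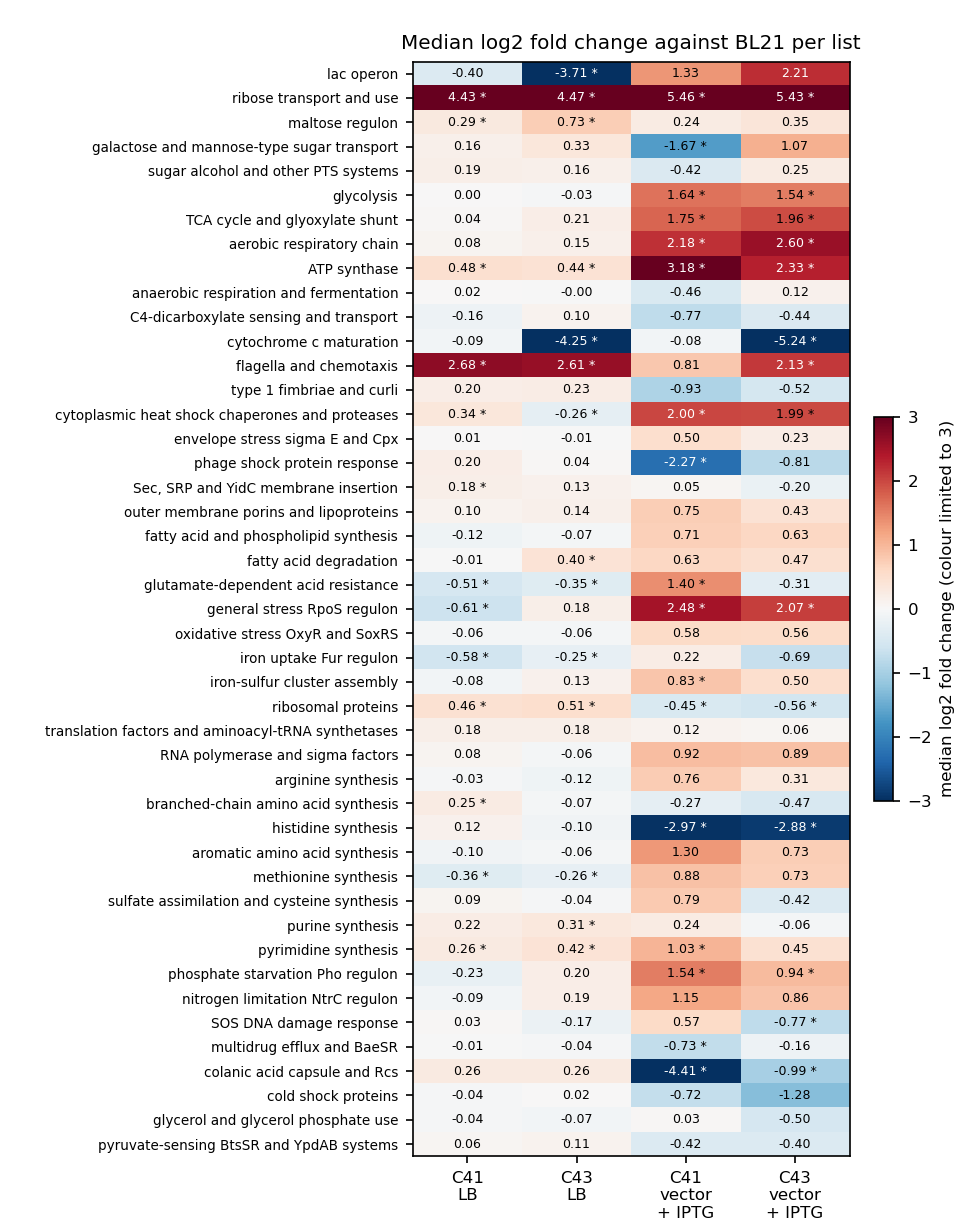
Median log2 fold change against BL21 of each of 45 gene lists (colour) in 4 comparisons, with genes at 0 counts set to their bounds and an asterisk where camera with the preset correlation passed. Ribose genes reach medians from 4.43 to 5.46 in all 4 comparisons, and histidine genes are low with vector and IPTG in both strains.

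C43 against C41 with vector and IPTG asked which changes separated the derivatives under induction. The largest differences lay in the runs: genes of the C41 run were higher in C43, and genes of the C43 runs lower. In C43, yegE and yegQ were at least 406-fold and at least 396-fold higher, gatY was higher by 11.07 ± 0.30 (adjusted p = 1.26e-11), and yegP, with 1 to 3 C41 counts, by a ratio of 3610.0 (95% counting interval 999 to 29820.0). The gene ada was at least 160.6-fold lower and napH at least 123-fold lower, while yjiA fell by 9.76 ± 0.24 (adjusted p = 1.26e-11) and hsdR by 9.42 ± 0.30 (adjusted p = 3.64e-11). Of 3909 genes, 2387 were called, 1191 higher and 1196 lower in C43, and 999 changed at least 2-fold. Upper-quartile scaling gave 1505 higher and 922 lower, and moved the median of all genes from 0.01 to 0.20.

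Loci chosen before the data were examined had mixed results in LB. There, lacA and lacY fell in C41 by 0.77 ± 0.15 and 0.64 ± 0.16; the lacY call was lost without BL21 replicate 1 (-0.57). The gene yjiY rose by 1.48 ± 0.20 in C41 and fell by 6.71 ± 0.25 in C43. The sensor gene yehU rose by 0.52 ± 0.12 in C41 and stood at -0.02 ± 0.12 in C43, and the oxidase gene cydA fell by 0.91 ± 0.14 in C43 and stood at -0.21 ± 0.14 in C41. In C41 lacZ (-0.23 ± 0.15, adjusted p = 0.326) and lon (0.07 ± 0.11, adjusted p = 0.688) were not called. In neither strain were fur, proY, yhhA and melB called, though fur in C41 was called without BL21 replicate 2 (-0.41). The cytochrome c maturation gene ccmF fell by 3.24 ± 0.34 in C43 and stood at -0.52 ± 0.26 in C41 (adjusted p = 0.175). The gene yjcO fell by 0.52 ± 0.14 in C43 (adjusted p = 0.0115), a call lost without BL21 replicate 3 (-0.38) or C43 replicate 3 (-0.46). In C41 yjcO stood at -0.40 ± 0.14 (adjusted p = 0.0542), called without BL21 replicate 2 (-0.50) or C41 replicate 3 (-0.52). Both lacI copies were not called in C41.

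Under vector and IPTG the same loci differed more widely. The gene lacY rose by 1.86 ± 0.11 in C41 and 2.76 ± 0.11 in C43, and lacA by 0.80 ± 0.14 and 1.82 ± 0.15, while lacZ stood at -0.23 ± 0.12 in C41 (adjusted p = 0.0809) and -0.05 ± 0.12 in C43 (adjusted p = 0.728). For lacI, of which the vector carries a further copy, counts assigned to ECD_10002 rose by 2.33 ± 0.37 and 2.60 ± 0.37; reads of the vector's copy were not told apart from it. The gene lon stood at -0.41 ± 0.20 in C41 (adjusted p = 0.0823); under upper-quartile scaling lacZ and lon in C41 were called at -0.54 and -0.72, and lon was also called without BL21 replicate 3 (-0.61). The transporter gene melB rose by 5.70 ± 0.14 in C41 and 3.13 ± 0.13 in C43, and yhhA by 3.26 ± 0.13 and 2.21 ± 0.13. The gene yjiY rose by 5.36 ± 0.48 in C41 and fell by 3.76 ± 0.46 in C43, cydA rose by 0.68 ± 0.12 in C43, and proY fell by 1.36 ± 0.14 in C41 and 1.56 ± 0.14 in C43. In C41 cydA stood at 0.28 ± 0.12 (adjusted p = 0.0468), at -0.02 under upper-quartile scaling, and uncalled without BL21 replicate 1 (0.25) or 2 (0.24) or C41 replicate 1 (0.32), 2 (0.31) or 3 (0.25). The iron regulator gene fur rose by 0.93 ± 0.17 in C43 and 0.51 ± 0.17 in C41, where it stood uncalled at 0.21 under upper-quartile scaling, 0.44 without BL21 replicate 1 and 0.37 without BL21 replicate 3. The sensor gene yehU fell by 0.97 ± 0.12 in C41 and 0.40 ± 0.12 in C43, the latter uncalled without BL21 replicate 2 (-0.29). The gene yjcO rose by 0.90 ± 0.16 in C41 and stood at 0.18 ± 0.16 in C43 (adjusted p = 0.31). The gene ccmF fell by 4.36 ± 0.31 in C43 and stood at 0.11 ± 0.19 in C41 (adjusted p = 0.608). No values for rbsD, dcuS, ycgO or the vector's resistance gene were in the count tables.

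The effect of each strain was then compared between the parts, to ask whether strain differences depended on vector and induction. It differed in 2791 of 3959 genes for C41, 1430 with a more positive and 1361 with a more negative effect under vector and IPTG, and in 2450 genes for C43, 1306 and 1144. Upper-quartile scaling turned both balances, with 1181 more positive and 1642 more negative for C41 and 1164 and 1319 for C43. For C41 the acid resistance genes gadE and slp had effects larger by 8.34 ± 0.44 (adjusted p = 7.91e-13) and 7.52 ± 0.37 (adjusted p = 2.19e-13) on the log2 scale; yjdN and tdcB followed at 7.63 ± 0.48 and 6.52 ± 0.33. For C43 the effect on lacY was larger by 6.65 ± 0.24 (adjusted p = 1.64e-14), moving from lower than BL21 in LB to higher with vector and IPTG. Under upper-quartile scaling the median difference over all genes moved from -0.07 to -0.36 for C41 and from -0.03 to -0.18 for C43. Across 3749 genes tested in both parts, the log2 fold changes of C41 in LB and with vector and IPTG had a correlation of 0.0107; 175 genes were higher in both parts (144.8 if calls were independent), 69 were lower in both (139.9), and 350 moved in opposite directions. For C43 the correlation was 0.465, with 259 higher in both (192.5), 188 lower in both (161.9) and 306 opposite. Both correlations include the genes of the runs, near absent in C41 with vector and IPTG alone but in C43 largely in both parts. They were not computed without these genes, so they do not compare how far effects outside the runs carried over. Between the strains with vector and IPTG, 1121 genes were higher and 1112 lower in both C41 and C43 (538.6 and 561.4 if independent), and 206 were opposite. Shared BL21 libraries can raise this overlap too, by an amount that was not measured. The correlation of C41 and C43 fold changes was 0.571, against 0.662 ± 0.0166 (SD, 50 simulations) in groups simulated without change, with covariances of 1.89 and 0.0459. It was 0.6 against different single BL21 libraries, a value from differences of log2 CPM rather than fitted fold changes.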

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

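All tests weighed in this part were chosen after the results were seen, except the genomic DNA test and the exchanges of labels between groups, which were written before.

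Strain effects that differed between the parts drew attention by a test of the interaction itself: 2791 genes for C41 and 2450 for C43. For C41 the largest differences, vector and IPTG minus LB on the log2 scale, were gadE (8.34), yjdN (7.63), slp (7.52) and tdcB (6.52), and at the counting floor yegQ (-10.31), yegU (-8.51), yegI (-8.30) and yegE (-7.34). For C43 they were garL (7.75), lacY (6.65), garR (6.61) and tnaC (6.24), with napH at the floor (-3.91), napA (-7.75, resting on 1 to 3 counts), yneM (-5.37) and mgtL (-4.82). Reads outside the main measurement also stood out in BL21 with vector and IPTG, where 76.67% of reads were unmapped and 49.75% of mapped reads lay outside coding sequences. In BL21 LB replicate 3, 68.5% of reads had low mapping quality.

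Exchanging labels within 6 libraries allows only 10 splits, too few for a share under 0.05. For genes called, the real grouping gave 737, 977 and 600 in LB and 3022, 2846 and 2387 with vector and IPTG, for C41 against BL21, C43 against BL21 and C43 against C41. In each of these 6 comparisons only 1 split, the real one, was as large, and the highest other split gave 0. At an unadjusted p under 0.05 the same edgeR test gave at most 301, 321, 213, 81, 87 and 75 genes in the other splits. Every other split mixed the strains in both groups, so strain differences entered the spread and lowered the calls. The 0 in these splits therefore carries little weight against chance. For lists, the real 13 and 14 in LB and 17 in C41 with vector and IPTG stood beside 10, 11 and 11 in the highest other split (only the real one, 1 of 10, as large in each). The 14 lists of C43 with vector and IPTG were reached by 3 of 10 splits, the real one among them, the highest other giving 15. For the interactions only 1 of 100 splits, the real one, was as large as 2791, and likewise 1 of 100 as large as 2450. The highest others were 2615 and 2311. Labels were exchanged in each part separately, which also breaks up the strain effects within the parts. These splits therefore cannot show whether the interaction itself exceeds chance.

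The unmapped reads of BL21 with vector and IPTG may be RNA read from the plasmid by T7 RNA polymerase. The polymerase gene had at least 17.13 times the CPM of a derivative strain, and the highest unmapped share of BL21 in LB was 0.119%. Both values fit that explanation but bear on the unmapped reads only. The 49.75% of mapped reads that lay outside coding sequences aligned to the reference, and plasmid RNA was not tested as their source. A flat background of genomic DNA could hold at most 2.142% of the coding counts and did not account for these mapped reads. What else they were was not tested. Reads of another organism or of adapters cannot be told apart from plasmid RNA by the gap of 59.3 percentage points in unmapped share, because the reads themselves were not analysed here. A physiological difference of BL21 under induction remains untested.

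The near absence of wcaN to ECD_02037 in C41 with vector and IPTG was not a matter of depth: the BL21 libraries of the same part, with fewer assigned reads, held 68876 counts in the 44 genes where C41 held 663. Counts due at the share of C41 in LB were 538.8 times those observed, but that value takes the level in LB to hold with vector and IPTG, which the design cannot test. Libraries of BL21 or C43 under the C41 label did not account for it either: 0 of 4 marks of C41 were lacking. Whether the genes are missing from the cells or silent cannot be told from RNA; 21 of the 44 genes with a mean BL21 count of 10 or more had 0 counts in all 3 libraries, and DNA would be needed. A deletion arising in the culture that received the vector is a hypothesis and was not tested.

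The residue of about 1% in the C43 run genes in LB could be reads carried over from other LB libraries. Of 11 genes with 10 or more due counts, 10 in the LB runs plus napC from between ccmF and napF, 100% lay within 2-fold of the pooled ratio. That ratio came from the same genes, so the test restates an even residue and does not show its source. Cells that keep the region, mixed into the cultures at 1.018% of BL21, cannot be told apart from carry-over, because both give an even residue. Reads shared with similar genes were tested by a rank correlation of 0.753 (0.544 to 0.884 over resampled genes), which leaves them open. That test replaced an earlier version whose answer depended on whether yjiY was included, and its bounds were set after the values were seen, so it carries little weight. Carry-over did not account for ccmF to napF as a whole, napC included, where the counts were 7.55 times those due, a test added after the table was seen.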

How the results depend on the processing

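The thinned and run-free alternatives were chosen after the data were seen; the other tests were planned. The planned removal of rRNA and tRNA genes was not run, as the tables hold none. Of 10349 values for named genes 10209 kept their call or lack of one, 123 lost the call, 16 gained it and 1 reversed. The reversed value was cydA in C41 with vector and IPTG, where 0.28 became -0.0222 under upper-quartile scaling (adjusted p = 0.872). Direction was checked only where the main or the alternative fit called the gene. Of 984 list values 886 kept the call and 98 lost it. Of the 58 list calls followed, 52 were lost under at least 1 alternative. Of 276 counts and correlations 249 stayed within range and 27 moved. A fold threshold of 1 on the log2 scale left 137, 247 and 170 genes in LB (C41 against BL21, C43 against BL21, C43 against C41), and 1759 and 999 for the last 2 with vector and IPTG, by its construction. Camera with an estimated correlation called 2 and 4 lists in LB (C41, C43) and 0 and 0 with vector and IPTG; fry called 23, 25, 42 and 35. The correlation of C41 and C43 fold changes in LB moved from 0.4724 to 0.5355 with a mean CPM of 10 or more, 0.6939 without the gene runs and 0.3662 against different single BL21 libraries. With vector and IPTG it moved from 0.5714 to 0.582 with no filter, 0.5872 thinned, 0.7593 without the runs and 0.6004 against different BL21 libraries. The values against different BL21 libraries used differences of log2 CPM with a prior count of 2, not fitted fold changes. They therefore changed the measure as well as the controls. The cause of these moves was not tested.

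Leaving out 1 library gave 488 (without BL21 LB replicate 1) to 754 genes for C41 in LB, the only count moved by over 1.5 times; the cause was not tested. It gave 706 to 1054 for C43 in LB, 2851 to 3048 for C41 and 2631 to 2891 for C43 with vector and IPTG. The correlations ranged from 0.4451 to 0.5072 in LB and from 0.5639 to 0.5847 with vector and IPTG. With the replicate number as a replicate block, 619, 820 and 517 genes were called in LB and 2981, 2811 and 2330 with vector and IPTG; no same-number pair had a correlation over 0.1, and 1 of 18 pairings in LB and 6 of 18 with vector and IPTG were best with their own number, so the numbers were not treated as pairs. Thinned to the shallowest library, 635, 809 and 501 genes were called in LB and 2533, 2357 and 1740 with vector and IPTG; the depths were 4213837 and 1149011 counts.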

Other observations

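No further tests were added after the results were seen. With vector and IPTG, yjiY, which the mcrC to lgoT region of C43 contains, stood at 7.32% of the BL21 CPM but 0.178% of the C41 CPM by TMM-scaled sizes, as yjiY was higher in C41 than in BL21. The CPM of rbsA in the 3 BL21 LB libraries was 6.86, 6.17 and 13.4. The C43 residue over the run genes, as a share of the deepest BL21 library, was 0.829%, 1.06% and 0.645% in its 3 LB libraries.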
